A study of Mus musculus with 4 samples.

How the data were processed

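RNA was sequenced from cells sorted out of Rb1 and Trp53 deficient lung tumours of reporter mice, in 2 GFP-positive and 2 GFP-negative libraries. Per the labels' protocols, full-length cDNA was made from very small amounts of total RNA with an oligo(dT) primer and template switching (SMARTer), amplified by PCR, fragmented enzymatically, and sequenced in paired reads on an Illumina NovaSeq instrument. The kit as described does not mark the strand, so a gene and an overlapping antisense gene cannot be told apart. Amplification from little RNA can multiply single molecules or lose them, and the counts carry no molecular identifiers, so counting errors understate the true error.

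The authors deposited 1 table of 17746 gene symbols with whole-number counts for each library, per the file headers. The same table gives FPKM values (fragments scaled by gene length and library total) that the authors deposited for each library, per the file headers. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6, DESeq2 and edgeR were used and the build was mm10; which program made the counts, the annotation release and the handling of reads shared between genes are not given in the sources used here. Every symbol in the table had counts in at least 2 of the 4 libraries, as the values show, with 5625 in all 4, 9027 in 3 and 3094 in 2. Libraries held 51994432 to 73997175 counts. Groups were taken from the sample descriptions, which give the GFP status, because the sample titles and the series' design text name opposite groups as high in autophagic flux.

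Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10), which left 16301, and libraries were scaled with TMM factors of 0.722 and 0.944 for the GFP-positive and 1.54 and 0.956 for the GFP-negative libraries. A model with the group as its only term was fitted with glmQLFit, and GFP-negative was compared with GFP-positive by glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 change divided by the square root of the F statistic, so they rest on a spread moderated across genes. A fold against a group at 0 counts was computed against 3 counts per library, averaged over the group. With 2 libraries against 2, an exact permutation test cannot reach the threshold and was not used. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 31 lists with at least 5 tested members. Of the 32 lists, 24 were gene lists and 8 were markers of other cell types. Camera compares a list with all other genes, so its direction is relative to them. Positions came from GENCODE M21, which uses the same build, and 17315 symbols (97.6%) matched 1 annotated gene.

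The design, the lists and the rule for named genes were fixed before the data were examined. The rule took up to 10 genes with the largest change in each direction among calls whose groups did not overlap. Where fewer than 5 genes passed in a direction it was filled to 10 with the smallest unadjusted p among genes with a group mean of 5 CPM or more. It added fixed genes of small cell lung cancer, autophagy and the sort, and within each list up to 4 called members or, if none passed, the 2 with the smallest p. Of the genes this rule named, 2 are not reported here and not counted in the closing section; they stayed in every fit and list. Exceptions named after their values were seen are Alb, Apoe, Gm44805, the neighbours of Mycl and the genes so marked in the closing section.

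The scripts were tested on simulated counts drawn from the real means and library sizes. At a dispersion of 0.1, edgeR recovered 151 of 200 genes changed 4-fold and all 200 changed 16-fold. With the common dispersion of the data, 3.67, given to every gene, it recovered 0 of 200 at either size. Real genes differ in dispersion, so this is no measure of what the test can find in the data. At the dispersion of 0.1, a lysosome list lowered 4-fold in the simulation was called by camera, with 0 other lists called. Genes were drawn independently there, so this does not show how camera performs at the spread and correlation of the data.

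The alternatives fixed in advance were a replicate block, no filter, a filter of 20 counts in 2 libraries, DESeq2 size factors, DESeq2's Wald test (version 1.42.0), upper quartile scaling, limma-voom, limma on log2 FPKM with pseudocounts of 0.1 and 5, a 2-fold minimum, a threshold of 0.1, leaving out each library in turn, an estimated correlation in camera, and fry. Scaling by library totals, testing only genes with counts in all 4 libraries, and limma on FPKM with a pseudocount of 1 were added after seeing the data. With 1 library left in a group, the spread came from the other group. The GFP and RFP sequences were not analysed here.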

Results

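Gene expression was measured by RNA sequencing in cells sorted from Rb1 and Trp53 deficient lung tumours of mice, a genetic model of small cell lung cancer. The mice also carried a reporter of autophagy, the GFP-LC3-RFP-LC3ΔG probe, which is cut in the cell into a GFP-LC3 part that autophagy degrades and an RFP part that stays in the cytosol. Live cells positive for the epithelial surface protein EpCAM and for RFP were divided into GFP-positive and GFP-negative cells, with 2 libraries of each. The comparison asks which genes differ between tumour cells of unequal autophagic flux. The sources conflict on its direction: the sample titles give high flux to the GFP-positive libraries, and the design text of the series gives it to the GFP-negative cells. Since autophagy degrades the GFP part, the probe itself goes with the design text. The labels do not show whether the flux or the GFP status is misnamed. The groups are therefore named by GFP alone, every change is GFP-negative minus GFP-positive, and no direction is drawn for flux. Nothing in the labels says that the 2 libraries of a group came from separate animals. The p-values thus speak only to these libraries, whose spread may be technical. edgeR moderates the spread of each gene across genes, so a small SE or p does not show that the 2 libraries of a group agree.

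The 2 GFP-positive libraries held 51994432 and 67536465 counts and the 2 GFP-negative libraries 73997175 and 69676412, for replicates 1 and 2 in that order. Counts were found for 6063 of the 17746 gene symbols in GFP-positive replicate 1, against 16379 in GFP-positive replicate 2, 17617 in GFP-negative replicate 1 and 15710 in GFP-negative replicate 2. The 100 most abundant genes took 37.0% and 36.8% of the counts in the GFP-positive libraries and 17.2% and 31.1% in the GFP-negative libraries. Below, levels are CPM, counts normalised to the TMM-scaled size of each library, given for replicates 1 and 2 of a group in that order. At 0 counts, a limit of 3 counts equals 0.080 and 0.047 CPM in the GFP-positive and 0.026 and 0.045 CPM in the GFP-negative libraries, for counting error only. Across 16301 genes, which are not independent replicates, Pearson's correlation of log2 CPM was 0.44 between the GFP-positive libraries and 0.63 between the GFP-negative libraries. Between groups it reached 0.69 for GFP-positive replicate 2 with GFP-negative replicate 1 and 0.66 with GFP-negative replicate 2. This order depends on the measure: Spearman's correlation was 0.73 and 0.80 for these pairs and 0.69 for the GFP-negative pair, and Pearson's over genes at 5 CPM or more in 2 libraries 0.49, 0.67 and 0.46. GFP-positive replicate 1 correlated at 0.36 and 0.41 with the GFP-negative libraries, and the first principal component, with 80.9% of the variance, set it apart from the other 3.

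Some genes typical of macrophages, red blood cells and lysosomes were called lower in the GFP-negative libraries: 3 of 23 macrophage markers, 2 of 6 erythroid genes and 2 of 37 lysosomal genes, in lists that did not pass with an estimated correlation (adjusted p = 0.495, 0.524 and 0.339). Chil3, a chitinase-like protein of macrophages, stood at 42910 and 6561 CPM in GFP-positive and 186 and 1207 CPM in GFP-negative libraries, a log2 change of -5.15 ± 0.54 (SE, n = 2 per group, edgeR adjusted p = 1.8e-17), and -3.24 without GFP-positive replicate 1. Lyz2, the lysozyme of myeloid cells, fell from 43154 and 19819 to 480 and 8635 CPM (log2 change -2.79 ± 0.43, edgeR adjusted p = 2.22e-07). Ctss, a cathepsin of antigen-presenting cells, fell from 12505 and 8943 to 194 and 2305 CPM. The lysosomal proteases Ctsd and Ctsb had log2 changes of -4.30 ± 0.87 and -2.57 ± 0.54, with edgeR adjusted p = 0.00234 and 0.00312. Ctsb stood at 13819 and 18719 CPM in GFP-positive and 494 and 4969 CPM in GFP-negative libraries, so its size depends on the GFP-negative library. The globin genes Hbb-bs and Hba-a1 had log2 changes of -4.04 ± 0.85 and -2.86 ± 0.61, and of -2.79 and -1.87 without GFP-positive replicate 1. Fth1, the heavy chain of the iron store ferritin, lay at 15661 and 13459 CPM in GFP-positive and 554 and 3758 CPM in GFP-negative libraries. In all of these genes both GFP-negative libraries lay below both GFP-positive libraries.

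edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 16 of 16301 genes, 15 lower and 1 higher in GFP-negative libraries. The libraries of the 2 groups did not overlap for 14 of the 15 lower calls and for the higher one. Over all tested genes 31.8% had groups that did not overlap, where chance gives 33.3%. At an unadjusted p under 0.05 there were 505 genes, 381 higher and 124 lower. The median log2 change of all tested genes was 0.91 under TMM scaling, and 1.12, 0.43 and 1.33 under DESeq2 size factors, upper quartile and library totals. Among tested genes with counts in all 4 libraries, fitted alone, it was -0.06. The shift thus rests on genes at 0 counts in some library and is no baseline for genes with counts in all 4. Camera compares a list with all other genes, on log2 CPM of each library and not on these fitted changes. In limma-voom, which also uses log2 CPM, the median of all tested genes was 3.81. Camera's directions thus carry a shift of another size than 0.91, which was not measured on its own scale. The spread was wide: the common biological coefficient of variation was 1.92. In simulated data where every gene had that spread, edgeR recovered 0 of 200 genes changed 16-fold. Real genes differed in spread, and Lyz2 was called at a log2 change of -2.79 with an SE of 0.43. The simulation thus cannot show which changes the test would miss in these data. Without GFP-positive replicate 1 the test kept 1 of the 16 calls and made no other, without GFP-positive replicate 2 it called 7601 genes, and without GFP-negative replicate 2 it called 59. DESeq2's Wald test called 61 genes, 48 of them higher, of which 4 were among the 16, while limma-voom called 4 genes and upper quartile scaling 0, with 1150 genes at an unadjusted p under 0.05.

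The call kept without GFP-positive replicate 1, named here after its values were seen, was the gene model Gm44805. Its levels were 601 and 136 CPM in GFP-positive libraries, with 0 counts in both GFP-negative libraries. In that refit its own spread came only from the GFP-negative pair, both at 0 counts. Gm44805 is thus not shown to be more robust than the other calls. It lies on chromosome 7 (mm10) from 19671584 to 19681423, beside Apoc1, which starts at 19689481, and Apoe, which starts at 19696109. Apoc1 and Apoe, whose products are apolipoproteins of lipid transport, had log2 changes of -7.65 ± 1.62 and -1.88 ± 0.46 (edgeR adjusted p = 0.00312 and 0.0434), with -3.35 for Apoc1 without GFP-positive replicate 1. Apoe stood at 18155 and 24095 CPM in GFP-positive and 112 and 11345 CPM in GFP-negative libraries. Ctsk, a lysosomal protease known from osteoclasts, lay at 3663 and 115 CPM in GFP-positive and 14.7 and 4.07 CPM in GFP-negative libraries, a log2 change of -7.65 that was -3.63 without that library.

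Several of the lower calls were set by GFP-positive replicate 1. Apoa2, an apolipoprotein made mainly in the liver, had 18132 CPM there, 3.09 CPM in GFP-positive replicate 2, and 0.35 and 0.48 CPM in the GFP-negative libraries (log2 change -14.41 ± 1.14, edgeR adjusted p = 3.83e-32). Without that library its log2 change was -2.89. Cyp2e1, a cytochrome P450 of the liver, had 1970 CPM in GFP-positive replicate 1, 0.82 CPM in replicate 2 and 0 counts in both GFP-negative libraries, so its mean was at least 27566-fold lower in the GFP-negative group, taking 3 counts per library as the limit. Alb, which encodes serum albumin, was at 5080 and 0 CPM in GFP-positive and 0.14 and 0.060 CPM in GFP-negative libraries, the only call whose groups overlapped. Without GFP-positive replicate 1 it had 0 counts in the GFP-positive library left, against 16 and 4 in the GFP-negative libraries, too few to measure a change.

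**Figure D1:**
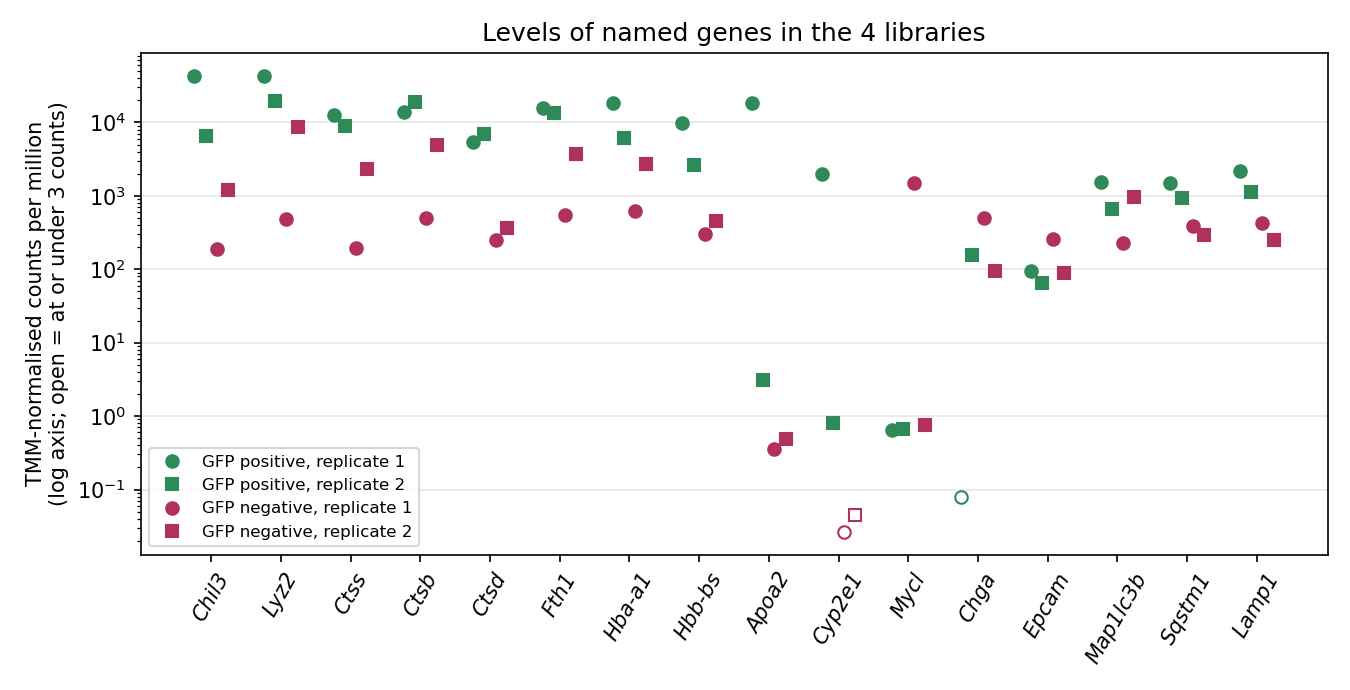
Levels of named genes in each of the 4 libraries, as TMM-normalised CPM on a log axis. Green marks GFP-positive and red GFP-negative libraries, circles replicate 1 and squares replicate 2, and open symbols values at or under 3 counts, drawn at that limit. Chil3 to Hbb-bs lie lower in both GFP-negative libraries, Apoa2 and Cyp2e1 are high in GFP-positive replicate 1 and Mycl in GFP-negative replicate 1.

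Mycl, a MYC-family transcription factor known as an oncogene of small cell lung cancer, was the 1 gene called higher in the GFP-negative group, and a single library set it. It stood at 1477 CPM in GFP-negative replicate 1, against 0.77 CPM in GFP-negative replicate 2 and 0.64 and 0.66 CPM in the GFP-positive libraries (log2 change 10.15 ± 2.46, edgeR adjusted p = 0.0412). The call ended without GFP-negative replicate 1, where the log2 change was 0.24 (edgeR adjusted p = 1.0), and also without GFP-positive replicate 1, where it was 10.12. Mycl lies on chromosome 4 (mm10) from 122995652 to 123002485. The other 4 genes within 200 kb that reached 5 CPM in some library were Ppt1, Cap1, Trit1 and Ppie. Their median log2 difference between GFP-negative replicates 1 and 2 was 5.76, at the 99.97th percentile of 9290 such windows around other genes, whose median was 0.30. Ppie, for example, had 1375 CPM in GFP-negative replicate 1 and 33.1 CPM in replicate 2. Between GFP-positive replicates 1 and 2 the median of the same neighbours was 2.36, at the 99.38th percentile of windows, whose median was -2.94, with Trit1 at 700 and 12.02 CPM and Cap1 at 0.24 and 1.80 CPM.

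**Figure D2:**
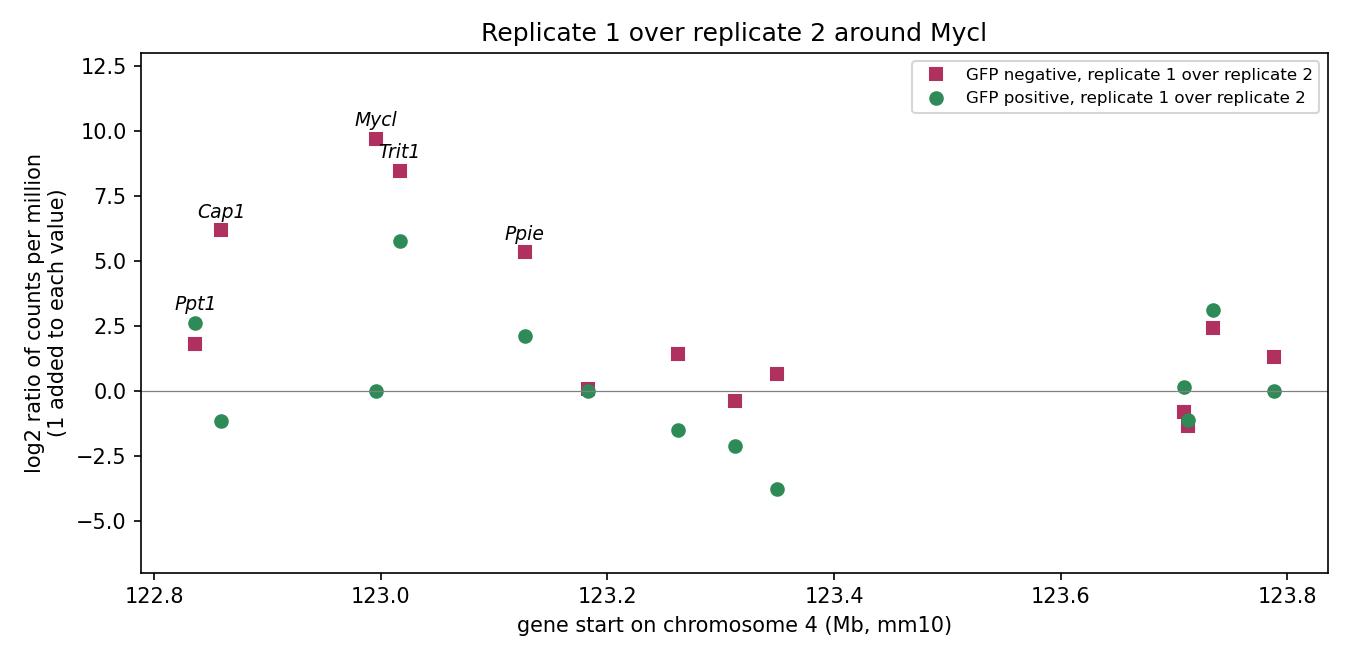
Log2 ratio of replicate 1 over replicate 2 for genes around Mycl, by gene start on chromosome 4 (mm10), in the GFP-negative libraries (squares) and the GFP-positive libraries (circles), with 1 CPM added to each value. Mycl and its neighbours Ppt1, Cap1, Trit1 and Ppie lie above 0 in the GFP-negative pair, and in the GFP-positive pair Ppt1, Trit1 and Ppie do, while Mycl lies near 0.

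No other gene passed on the higher side. Of the 9 genes there with the smallest unadjusted p, among those with a group mean of 5 CPM or more and groups that did not overlap, 8 were immunoglobulin genes, the products of B cells and plasma cells. Igkv5-39 stood at 0 counts in both GFP-positive libraries and at 23.4 and 372 CPM in the GFP-negative libraries, at least 3111-fold higher in the group mean, with edgeR adjusted p = 0.448. Igkv6-15 had 0.053 and 8.66 CPM in GFP-positive and 169 and 545 CPM in GFP-negative libraries, and Igha 0 and 98.4 against 236 and 1308 CPM (edgeR adjusted p = 1.0 for both). Igkv12-44 had values of 1.08 and 338 CPM in the GFP-negative libraries. Ighg1, Igkv8-27, Ighv1-26 and Ighv5-17 had 0 counts in both GFP-positive libraries, as had Vwf, a protein of endothelial cells, at 86.9 and 10.5 CPM in the GFP-negative libraries. In other fits some of these passed. DESeq2's Wald test called Igkv5-39, Ighg1, Ighv1-26, Ighv5-17, Vwf and Igkv8-27 higher (DESeq2 adjusted p = 0.00452 to 0.0231), and limma on FPKM with a pseudocount of 1 called Igkv6-15 and Igkv5-39 (limma adjusted p = 3.01e-04 and 0.00903). No list of immunoglobulin genes was fixed or tested. Similar variable segments can share reads, so the split among them is uncertain, as it is between the near-identical globin copies.

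Tumour identity was read from fixed genes. Epcam, the gene of the sort marker, was present in every library, at 94.0 and 65.9 CPM in GFP-positive and 255 and 88.9 CPM in GFP-negative libraries. Trp53 had 20.4 and 62.6 against 13.1 and 4.37 CPM and Rb1 0 and 4.06 against 8.996 and 0 CPM. Gene-level counts cannot show the recombined exons, so these 2 genes do not check the deletion. Ptprc, the CD45 gene of blood cells, had 0 and 79.9 against 22.0 and 18.4 CPM. Of the neuroendocrine genes, Chga was present in 3 libraries and had no counts in GFP-positive replicate 1 (0 and 156 against 494 and 94.1 CPM). Calca, present in all 4, had 3073 and 350 against 2744 and 489 CPM. Neither passed the test, with log2 changes of 1.92 ± 2.14 for Chga and -0.08 ± 0.97 for Calca. Rest, Hes1 and Myc had log2 changes of 0.15 ± 4.44, -1.83 ± 3.35 and -2.60 ± 3.03, the mesenchymal genes Vim and Cd44 of -3.59 ± 2.27 and -3.99 ± 2.92, and the proliferation genes Mki67 and Top2a of 2.36 ± 4.16 and 1.96 ± 3.32. The log2 changes without GFP-positive replicate 1 were 0.91 for Chga, 2.201 for Calca, -0.84 for Rest, -0.52 for Myc, -2.09 for Vim, -1.69 for Cd44, 1.36 for Mki67 and 1.02 for Top2a. Neurod1, Pou2f3 and Yap1 were looked up and were not among the 17746 symbols of the authors' table, so they could not be tested. Why they are missing is not given, so no level is drawn from it.

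Of the genes of autophagy itself, none passed the test. In the list of core machinery, 0 of 36 members were called and 27 had a fitted change above 0. The median fitted log2 change was 1.07 (interquartile range 0.005 to 1.65), near the 0.91 of all genes. Camera, on its own log2 scale, did not call the list (camera adjusted p = 0.805). In GFP-positive replicate 1, 20 members had 0 counts, and without it the median was 0.55, against 0.29 for all genes. Uvrag and Atg5, the members with the smallest p, had log2 changes of -4.31 ± 2.74 and -2.63 ± 2.15, and of -1.23 and 0.13 without GFP-positive replicate 1. Among 16 autophagy receptors 0 were called (median 0.84, and 0.27 without GFP-positive replicate 1, camera adjusted p = 0.292, directed downward against a positive median). Sqstm1, the cargo receptor p62, had 1514 and 932 against 384 and 292 CPM (log2 change -1.86 ± 1.31), and Ncoa4, the ferritin receptor, -3.36 ± 2.47, and -0.72 without GFP-positive replicate 1. Map1lc3b had 1548 and 672 against 225 and 973 CPM (-0.89 ± 1.24) and Map1lc3a a log2 change of 0.47 ± 1.60, and these 2 were at -0.17 and -0.26 without GFP-positive replicate 1. Reads from the LC3 part of the reporter were not told apart from the endogenous gene. Tfeb, a regulator of lysosomal genes, had 0 and 33.4 against 3.75 and 2.42 CPM.

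The lysosome list fell as a set in the camera test with its preset correlation (adjusted p = 3.18e-11), and not with an estimated correlation (adjusted p = 0.339). Of its 37 members 2 passed the gene-level test, Ctsd and Ctsb, and 4 when adjusted over the list alone. A fitted change below 0 was found for 35, with a median of -1.97 (interquartile range -2.57 to -1.31). Lamp1, a lysosomal membrane protein, had 2149 and 1133 against 431 and 250 CPM (log2 change -2.27 ± 1.22, edgeR adjusted p = 1.0). Without GFP-positive replicate 1 the median was -1.70 with 35 members below 0, 34 of them the same. The macrophage markers were lower across the groups too, but the 2 lists parted within the GFP-negative group, where replicate 2 differed from replicate 1 by a median log2 difference of 2.79 for the markers and -0.24 for the lysosomal genes. Between GFP-positive replicate 2 and GFP-negative replicate 2, all 37 lysosomal genes and all 23 macrophage markers were higher in the former, by a median log2 difference of 1.84 and 1.96, and between GFP-positive replicate 2 and GFP-negative replicate 1 the medians were 1.91 and 4.70. GFP-positive replicate 1 was higher than GFP-negative replicates 1 and 2 for only 26 and 24 of the 37 lysosomal genes and 19 and 18 of the 23 markers.

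The macrophage and myeloid markers had fitted changes below 0 for 23 of 23 members, 3 of them at 0 counts in GFP-positive replicate 1, with 3 called (Chil3, Lyz2 and Ctss), 15 adjusted over the list alone and a median log2 change of -2.79 (camera adjusted p = 1.37e-16, and adjusted p = 0.495 with an estimated correlation). They took 10.4% and 8.68% of the counts in GFP-positive and 0.339% and 3.25% in GFP-negative libraries. The 6 erythroid genes, 2 called and 4 adjusted over the list alone, had a median of -4.14 (camera adjusted p = 1.17e-07, and adjusted p = 0.524 with an estimated correlation), and -2.11 without GFP-positive replicate 1. Their share of the counts was 3.29% and 1.35% against 0.241% and 0.516%. Antigen presentation by MHC class I had 17 of 18 members below 0, 0 called and 2 adjusted over the list alone. Its median was -1.35 (camera adjusted p = 3.96e-06, and adjusted p = 0.339 with an estimated correlation), and B2m and H2-D1 had log2 changes of -2.97 ± 0.81 and -2.68 ± 0.77 (edgeR adjusted p = 0.194 and 0.380). Interferon response genes had 24 of 26 members below 0 and none called (median -1.56, camera adjusted p = 0.0414, and adjusted p = 0.941 with an estimated correlation). Of these 26, 19 had 0 counts in GFP-positive replicate 1. The list's median level was 0 and 71.9 CPM in GFP-positive and 6.40 and 31.7 CPM in GFP-negative libraries. Most of the fall thus rests on GFP-positive replicate 2, and without it camera pointed upward. Irf7 and Ifit1 had log2 changes of -2.59 ± 2.64 and -2.07 ± 2.18 (-1.21 for Ifit1 without GFP-positive replicate 1). This call ended without GFP-positive replicate 2 or GFP-negative replicate 1 (camera adjusted p = 0.666 and 0.430), and with the replicate numbers as a block (0.154). The immediate early and dissociation genes, with Junb at -2.63 ± 1.16 and Atf3 at -2.92 ± 1.42, had a median of -1.03 and 0 of 23 called (camera adjusted p = 6.97e-07, and adjusted p = 0.339 with an estimated correlation).

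**Figure D3:**
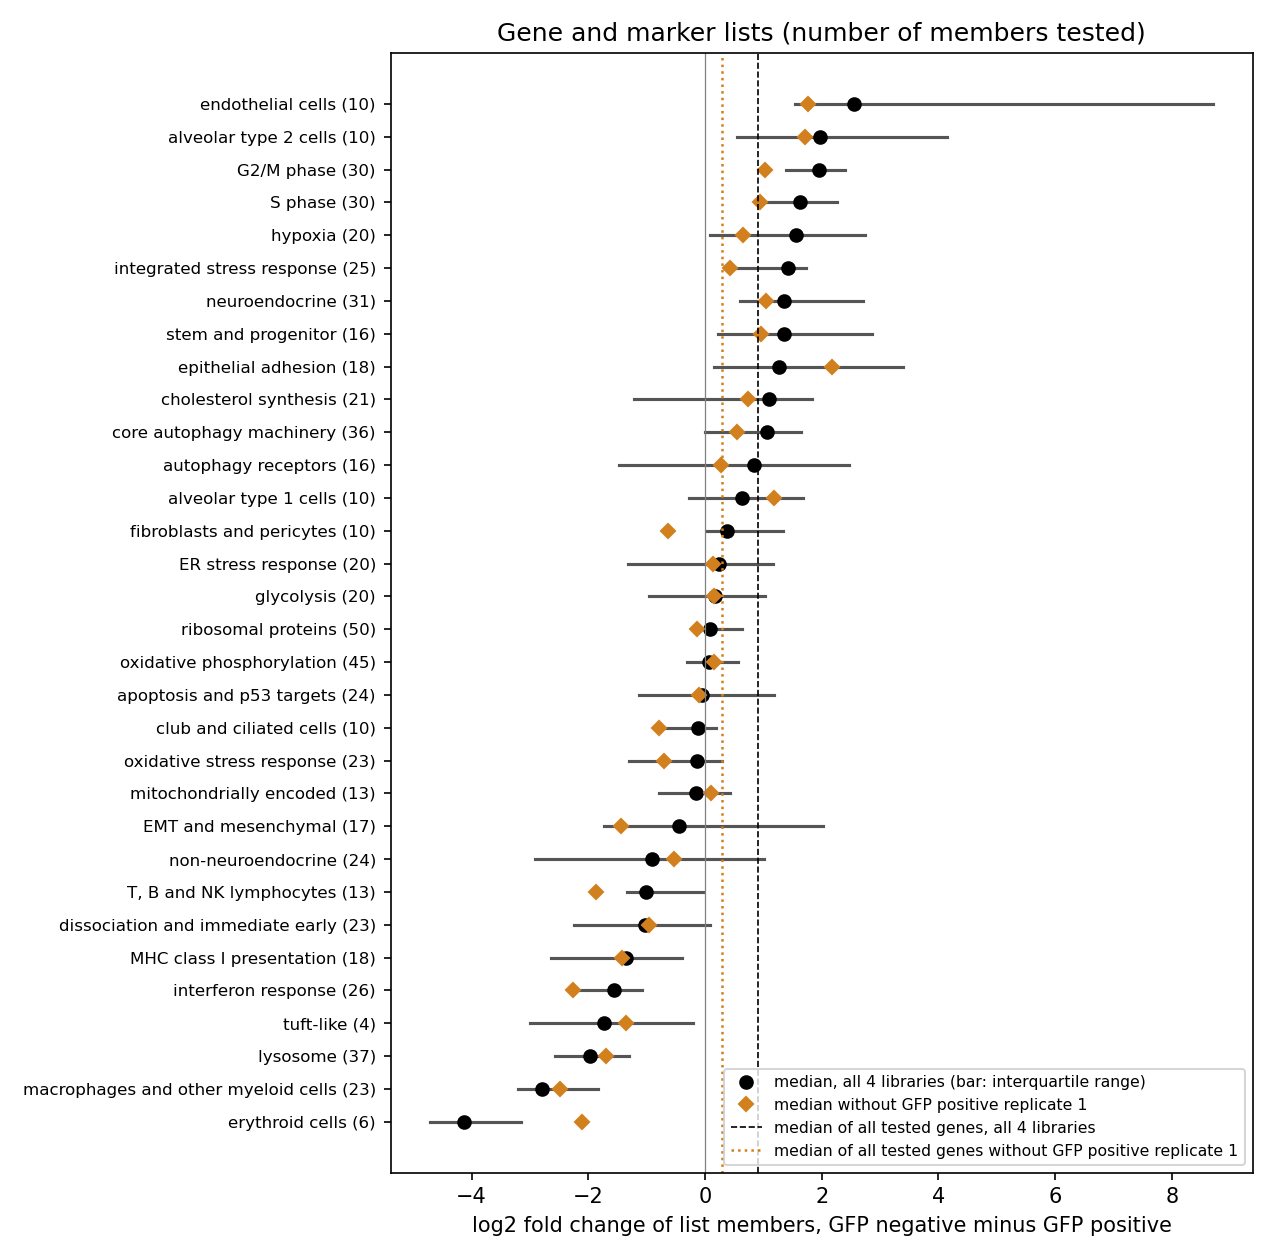
Median log2 change (GFP-negative minus GFP-positive) of each gene and marker list, with its interquartile range over members as a bar and the number of tested members in brackets. Diamonds give the median without GFP-positive replicate 1, the dashed line the median of all tested genes (0.91) and the dotted line the same without that library (0.29). The lysosome list lies at -1.97 and the macrophage list at -2.79.

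Of the cell state lists, the neuroendocrine genes had 1 of 31 members called, Mycl, also when adjusted over the list alone, and a median log2 change of 1.36 with 28 above 0 (camera adjusted p = 0.0993). The list passed under a replicate block (camera adjusted p = 0.0420) and among genes with counts in all 4 libraries (camera adjusted p = 0.00217), and not with an estimated correlation over all tested genes (adjusted p = 0.941). Non-neuroendocrine genes had 0 of 24 called and a median of -0.92 (camera adjusted p = 4.6e-04, and adjusted p = 0.387 with an estimated correlation). Their members with the smallest p, Lgals3 and Anxa1, had log2 changes of -2.73 ± 1.02 and -3.50 ± 1.45, and without GFP-positive replicate 1 the list no longer passed (camera adjusted p = 0.0573), its median was -0.53 and Anxa1 was at -0.88. The 4 tuft-like genes were too few for the set test (median -1.74), with Alox5ap at -2.90 ± 1.96 (-1.12 without GFP-positive replicate 1) and Ptgs1 at -3.28 ± 4.43. Mesenchymal genes had 0 of 17 called, with a median of -0.45 and a mean of 0.38 (camera adjusted p = 0.722), and a median of -1.44 without GFP-positive replicate 1. Tgfbi had a log2 change of -4.37 ± 2.25 (-2.11 without that library) and Snai2 0 counts in both GFP-positive libraries against 27.0 and 8.26 CPM. Epithelial adhesion genes (0 of 18 called, median 1.26, and 2.18 without GFP-positive replicate 1, camera adjusted p = 0.668) included Cldn4 at 3.98 ± 3.33 and Cdh1 at 5.28 ± 4.80. GFP-negative replicate 1 set most of both sizes, with Cldn4 at 0.59 and 17.2 against 238 and 43.0 CPM and Cdh1 at 0.11 and 2.82 against 111 and 2.49 CPM. Stem and progenitor genes (0 of 16, median 1.36, camera adjusted p = 0.540) included Lin28b, with 0 counts in GFP-positive libraries and 1.06 and 2.78 CPM in GFP-negative libraries, and Nes at -3.95 ± 3.64.

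Cell cycle genes mostly had fitted changes above 0, and no single gene passed. All 30 G2/M genes had a fitted change above 0, with a median of 1.96 (camera adjusted p = 0.00216, and adjusted p = 0.941 with an estimated correlation). Bub1 and Cdk1 had log2 changes of 5.13 ± 5.29 and 1.84 ± 2.02. Of 30 S phase genes 25 were above 0 (median 1.63, camera adjusted p = 0.333, 0.0158 among genes with counts in all 4 libraries, and adjusted p = 0.941 with an estimated correlation), with Mcm2 at 3.01 ± 2.25 and Mcm6 at 2.62 ± 2.21. In GFP-positive replicate 1, 14 of the G2/M genes and 11 of the S phase genes had 0 counts. Without that library the medians were 1.03 and 0.94, against 0.29 for all genes, with Cdk1 at 0.84, Mcm2 at 2.01 and Mcm6 at 1.61. Mcm2 stood at 0.51 and 80.5 against 611 and 42.1 CPM and Mcm6 at 0.11 and 103 against 539 and 94.7 CPM. GFP-negative replicate 1 thus set the size of both, and GFP-negative replicate 2 lay below GFP-positive replicate 2. The G2/M call ended without GFP-negative replicate 2 (camera adjusted p = 0.169).

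Metabolic and stress lists had few or no called members. Glycolysis (median 0.18, camera adjusted p = 0.0447, and adjusted p = 0.578 with an estimated correlation), oxidative phosphorylation (0.08, camera adjusted p = 3.2e-04, and adjusted p = 0.911 with an estimated correlation) and ribosomal proteins (0.09, camera adjusted p = 0.00506, and adjusted p = 0.941 with an estimated correlation) had 0 of 20, 45 and 50 members called. The set test, which compares a list with all other genes, directed these 3 lists downward although their own medians were above 0. The 13 mitochondrially encoded genes had a median of -0.15 and 0 called (camera adjusted p = 0.0169, and adjusted p = 0.520 with an estimated correlation). Without GFP-positive replicate 1, or without GFP-negative replicate 1, none of these 4 lists passed (camera adjusted p = 0.712 to 0.905 and 0.0902 to 0.945), and without GFP-negative replicate 2 glycolysis and the mitochondrially encoded genes did not (0.228 and 0.0671). Examples were Pfkl at -1.84 ± 1.70, Tpi1 at 1.09 ± 1.47, Uqcrc1 at 1.82 ± 1.31, Cycs at 1.62 ± 1.19, Rpl12 at 1.71 ± 2.47, Rpl5 at -1.08 ± 1.60, mt-Nd1 at -0.89 ± 1.31 and mt-Nd6 at -1.50 ± 2.47. Fitted without GFP-positive replicate 1 these stood at 0.30, 0.61, 0.82, 1.27, 0.71, -0.09, -0.08 and 0.55 in the same order, and the medians at 0.15 for glycolysis, 0.15 for oxidative phosphorylation, -0.14 for ribosomal proteins and 0.11 for the mitochondrially encoded genes. In the oxidative stress list Fth1 was the 1 member called of 23, with 2 adjusted over the list alone, and the median was -0.13 (camera adjusted p = 0.00907, and adjusted p = 0.555 with an estimated correlation). It did not pass without GFP-positive replicate 1, where its median was -0.70, or without GFP-negative replicate 1 (camera adjusted p = 0.0590 and 0.0902). Hypoxia genes (0 of 20, median 1.56, camera adjusted p = 0.805) included Bhlhe40 at -2.88 ± 1.34 and Anxa2 at -2.75 ± 1.36, with -0.24 and -0.89 without GFP-positive replicate 1. The integrated stress response (0 of 25, median 1.42, camera adjusted p = 0.604) included Slc3a2 at -1.53 ± 1.39 and Slc7a5 at 3.84 ± 4.77. Slc7a5 had 0 and 4.85 against 66.0 and 3.59 CPM, so GFP-negative replicate 1 set most of its change. The ER stress response (0 of 20, median 0.24, mean -0.06, camera adjusted p = 0.0763) included Sdf2l1 at -2.83 ± 2.35 and Dnajc3 at -1.87 ± 1.77. Cholesterol synthesis (0 of 21, median 1.10, camera adjusted p = 0.668) included Hmgcs1 at -2.82 ± 2.19 and Acat2 at 2.77 ± 2.37. Apoptosis and p53 targets (0 of 24, median -0.06, mean 0.26, camera adjusted p = 0.269) included Mcl1 at -2.63 ± 2.28 and Trp53inp1 at 5.22 ± 5.27. Medians without GFP-positive replicate 1 were 0.66 for hypoxia, 0.42 for the integrated stress response, 0.14 for the ER stress response, 0.74 for cholesterol synthesis and -0.10 for apoptosis and p53 targets, with Sdf2l1 at -1.42, Dnajc3 at 0.64, Hmgcs1 at 0.73 and Acat2 at 1.77. For receptors, hypoxia, the ER stress response and cholesterol synthesis the set test pointed downward against a median above 0.

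Markers of other cells of the lung were read beside these lists. Endothelial markers had 8 of 10 above 0, 0 called and a median of 2.55 (camera adjusted p = 0.0433, and adjusted p = 0.790 with an estimated correlation). Pecam1 had 396 and 1.10 against 2.78 and 2.27 CPM. The call ended without GFP-positive replicate 2 or GFP-negative replicate 2 (camera adjusted p = 0.639 and 0.173), and under the replicate block (0.0898). Club and ciliated cell genes had 0 of 10 called and a median of -0.11 (camera adjusted p = 0.0421, and adjusted p = 0.885 with an estimated correlation), with Scgb1a1 at 2884 and 1264 against 301 and 529 CPM and Bpifa1 at 0.11 and 2845 against 17.8 and 5332 CPM. This call ended without GFP-positive replicate 2 or GFP-negative replicate 1 (camera adjusted p = 0.213 and 0.991), and under the replicate block (0.0898). Alveolar type 2 genes had a median of 1.97 (0 of 10, camera adjusted p = 0.358), with Sftpc at 147 and 192 against 82.4 and 2276 CPM and Sftpb at 4.598 ± 4.06. Alveolar type 1 genes had a median of 0.64 (0 of 10, camera adjusted p = 0.934), with Pdpn at -2.70 ± 4.12 and Clic5 at 0 counts in GFP-positive libraries. Fibroblast and pericyte genes had a median of 0.37 (0 of 10, camera adjusted p = 0.934), with Col1a2 at 4.82 ± 3.97 and Tagln at 1.55 ± 2.84. Lymphocyte genes had a median of -1.004 (0 of 13, camera adjusted p = 0.292, 0.00178 without GFP-positive replicate 1, and adjusted p = 0.941 with an estimated correlation), with Cd2 at -4.33 ± 2.79. With GFP-positive replicate 1 left out the medians were -1.87 for lymphocyte, -0.63 for fibroblast and pericyte, 1.18 for alveolar type 1 and -0.80 for club and ciliated cell genes, with Cd2 at -1.87, Pecam1 at 1.19, Pdpn at 2.53 and Tagln at 0.56. None of the 15 list calls of the camera test held with an estimated correlation or in fry's directional test, where the lowest adjusted p was 0.339 and 0.840.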

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

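Library totals, genes with counts in all 4 libraries and limma on FPKM with a pseudocount of 1 were chosen after seeing the data, and the cause of the changes below was not tested. Differences between replicates 1 and 2 correlated at -0.073 across genes between the groups. GFP-positive replicate 1 lacks counts for most genes, but over the 5492 tested genes with counts in all 4 libraries the value was -0.074. Neither value can exclude a shared tumour, since amplification from little RNA can hide a shared difference. Labels give no shared animal for the replicate numbers. With them as a replicate block edgeR called 21 genes, 0 higher, 12 of them among the 16. The count of 16 (1 higher, 15 lower) was 14 to 19 with no filter, 20 counts in 2 libraries, DESeq2 size factors and library totals (3 higher with totals). A 2-fold minimum or a threshold of 0.1 left it at 16. It was 61 (48 higher) in DESeq2's Wald test, which gave no adjusted p for 4473 genes, 0 (0 higher, 0 lower) under upper quartile scaling, which rests on the upper quartile of each library, with 34.2% of genes above 0 in GFP-positive replicate 1, 4 in limma-voom (0 higher, 4 lower), and 5 (4 lower) among genes with counts in all 4 libraries. On FPKM it was 15 (5 higher), 34 (13 higher) and 8 (4 higher, 4 lower) with pseudocounts of 1, 0.1 and 5. Leaving out 1 library gave 1 to 7601 calls, with 0 to 7182 higher and 1 to 419 lower, the lowest without GFP-positive replicate 1 and the highest without GFP-positive replicate 2. Named genes past the test kept their sign in all 201 refits and lost the call in 84. Of 1193 refits of named genes not past it, 55 passed, 4 of them with the sign changed, and 54 changed sign. Without GFP-positive replicate 1, the log2 change of 44 of 91 named genes, 6 of them among the 13 past the test, was under its size with all 4 libraries divided by 1.5, or changed sign. The groups of those 13 genes did not overlap, so their kept sign was nearly fixed beforehand in refits that leave out a library. The correlation of the GFP-positive libraries was 0.42 by Spearman and 0.43 over genes at 5 CPM or more in 2 libraries. Depth limits only levels under 0.080 CPM, at 3 counts in the shallowest library.

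Of the lists, 15 passed in camera, 0 with an estimated correlation, 0 in fry and 8 to 12 with a library left out. The lysosome, macrophage, erythroid, MHC class I and immediate early lists passed in every camera fit with the preset correlation. Among lists not past camera, the neuroendocrine list passed under the replicate block and with counts in all 4 libraries, S phase with counts in all 4 libraries and lymphocytes without GFP-positive replicate 1. Lost were interferon, endothelial and club cells under the block, glycolysis with no filter, glycolysis and the mitochondrially encoded list with library totals, and these 2, oxidative phosphorylation, ribosomal proteins, oxidative stress and club cells with counts in all 4 libraries. As signed -log10 p (positive when higher in GFP-negative), fry, which tests a list against no change and not against other genes, so that its sign is another quantity than camera's, gave glycolysis 0.18, oxidative phosphorylation 0.044, ribosomal proteins 0.19, oxidative stress 0.042, interferon 0.071 and club cells 0.029. Both fry and camera used log2 CPM of each library, so their sign can differ from a list's fitted median, as fry's did for interferon (-1.56). In camera, genes with counts in all 4 libraries turned ribosomal proteins to 0.15. Over left-out libraries the mitochondrially encoded list ranged from -3.64 to 0.043, interferon from -8.87 to 0.22 and club cells from -4.33 to 0.00395.

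The genes that changed sign did not pass the test with all 4 libraries. In the refit that turned the sign, 4 passed: Ptprc, Ptgs1 and Irf7 without GFP-positive replicate 2, against a group at 0 counts, and Bpifa1 without GFP-negative replicate 2 (edgeR adjusted p = 0.0122, 0.0460, 0.0112 and 0.00408). Calca turned to 0.16 under the replicate block, 0.10 with DESeq2 size factors, 0.14 in the Wald test, 1.48 in limma-voom, 0.88 with library totals, 0.051 with counts in all 4 libraries and 0.71, 0.71 and 0.70 on FPKM (pseudocounts 1, 0.1 and 5). The block gave 2.61 for Tfeb, 4.61 for Ptprc, 2.43 for Ptgs1 and 3.13 for Irf7, and limma-voom 2.53, 4.76, 2.50 and 3.33, with -0.18 for Map1lc3a. On FPKM Ptprc was 0.04 and 1.07 (pseudocounts 1 and 0.1) and Irf7 0.99 (0.1). Upper quartile scaling gave -0.78 for Rest, -5.15 for Epcam, -0.69 for Top2a, -3.92 for Map1lc3a, -4.19 for Tpi1, -3.79 for Cycs, -1.82 for Col1a2 and -2.83 for Sftpc, and Tagln was -1.67 with counts in all 4 libraries. Over left-out libraries the log2 change ranged from -1.15 to 5.99 for Rest, -1.81 to 2.201 for Calca, -9.83 to 11.35 for Rb1, -3.44 to 10.81 for Tfeb, -0.88 to 1.99 for Map1lc3a, -1.99 to 13.52 for Ptprc, -3.52 to 0.13 for Atg5, -4.29 to 11.51 for Ptgs1, -9.15 to 5.58 for Nes and -2.67 to 0.30 for Pfkl. It ranged from -2.31 to 0.55 for mt-Nd6, -3.08 to 0.64 for Dnajc3, -5.32 to 0.73 for Hmgcs1, -4.88 to 14.24 for Irf7, -7.99 to 13.59 for Trp53inp1, -7.30 to 1.19 for Pecam1, -6.30 to 8.22 for Tagln, -0.996 to 3.75 for Sftpc, -3.68 to 2.53 for Pdpn and -6.34 to 14.59 for Bpifa1. Where the only library left of a group had 0 counts, the fitted end of a range is no measured size. Against 3 counts in that library, the level in the other group was at least 56.3-fold higher in GFP-negative for Rb1 (and at least 45.1-fold lower at the other end), 38.6-fold higher for Tfeb, 253-fold for Ptprc, 63.0-fold for Ptgs1, 417-fold for Irf7, 265-fold for Trp53inp1 (12.5-fold lower at the other end) and 6.39-fold for Tagln (3.83-fold lower at the other end). Nes was at least 28.0-fold lower at one end, and at the other the GFP-negative mean lay under the limit, so no fold is given. These limits allow for counting error only. The higher ends rest on GFP-positive replicate 1, where 21.3% of 788 genes at 100 CPM or more elsewhere lay under 1 CPM. GFP-positive replicate 2 exceeded both GFP-negative libraries for Tfeb (33.4 CPM), Ptprc (79.9 CPM), Ptgs1 (98.1 CPM) and Irf7 (401 CPM). For Rb1, Trp53inp1 and Tagln it lay between them.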

Other observations

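The tests on the drop-out, depth, scaling and left-out library below were chosen before their results were seen. Those on macrophage RNA and on Mycl were chosen only after the values they rest on were seen, as were the genes named in the next paragraph.

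Plasma cell and epithelial genes outside the fixed lists gave these levels. Jchain, the joining chain of secreted antibodies, stood at 0 and 202 CPM in GFP-positive and 213 and 1126 CPM in GFP-negative libraries (log2 change 2.73 ± 1.75, edgeR adjusted p = 1.0). Mzb1, a plasma cell chaperone, had 0 and 18.5 against 7.58 and 20.4 CPM, and Sdc1, which plasma and epithelial cells share, 0 and 38.9 against 54.8 and 26.2 CPM. The keratins Krt8 and Krt18 had 540 and 113 against 1406 and 217 CPM and 369 and 127 against 821 and 327 CPM, so they were present in every library. H2-Q10, a class I gene of the liver, had 1181 CPM in GFP-positive replicate 1 and 3.50, 1.04 and 0.18 CPM in the other 3 libraries.

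GFP-positive replicate 1 had counts for 6063 genes and the other 3 libraries for 15710 to 17617. Lower depth is argued against: thinned to the same total, the other 3 libraries kept counts for 15560 genes or more. A few genes taking most of the counts is argued against too, since outside the 100 most abundant genes, and thinned to the same remaining total, the others kept 15427 genes or more against 5963. Loss of transcripts before amplification remains a candidate explanation: of 788 genes at 100 CPM or more in the other 3 libraries, 21.3% lay under 1 CPM in this one, where the same measure gave 0%, 0.226% and 0% for the others. The sort of other cells, with the high Apoa2, Alb and Cyp2e1 of this library, was not tested as a cause.

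Most lysosomal genes had fitted changes below 0 in GFP-negative libraries, but only 2 of 37 passed on their own and the list did not pass with an estimated correlation (adjusted p = 0.339) or in fry (0.840). Scaling as the cause of the direction is argued against, since at least 89.2% of the 37 members were lower under each of 4 scalings. The size depends on it, with a median log2 change of -1.97 under TMM, -1.27 under library totals, -1.81 under DESeq2 size factors and -8.07 under upper quartile scaling. Argued against too is GFP-positive replicate 1 as the only source, since the median log2 change without it was -1.70 with an interquartile range of -2.56 to -1.11. Macrophage RNA, which an EpCAM and RFP gate should remove, is a candidate source. Lyz2 and Ctss stood at 480 and 194 CPM in GFP-negative replicate 1 and 8635 and 2305 CPM in replicate 2. Of the 23 markers, 22 reached 5 CPM in GFP-negative replicate 1, and 0 are on another list. Some, such as the cathepsin Ctss, are lysosomal themselves, so a share taken from the markers is not independent of lysosomal levels. With GFP-negative replicate 2 taken as replicate 1 plus a share of 0.194 of the step to GFP-positive replicate 2, as the markers show, its observed lysosomal levels stand to the mixed ones at a median log2 ratio of -0.87 (interquartile range -1.51 to 0.16), a range that holds both 0 and the -0.62 of replicate 1 unmixed. So the macrophage share and a difference between tumour cells by GFP cannot be told apart, because the tumour cells' own lysosomal level in each library is unknown.

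Mycl was high in GFP-negative replicate 1 alone. Over-amplification of a single cDNA as the whole cause is argued against, since the 4 neighbouring genes were higher there than in GFP-negative replicate 2, their median at the 99.97th percentile of windows. The neighbours did not all follow Mycl, which limits this argument. Ppt1 and Trit1 were higher still in GFP-positive replicate 1 (1605 and 700 against 594 and 352 CPM in GFP-negative replicate 1). Cap1 and Ppie were lower there (0.24 and 215 against 71.6 and 1375 CPM). A candidate explanation is a gain of this region in the tumour behind that library, a hypothesis that the DNA copy number of the region, not analysed here, would decide. Whether it follows the GFP status or the tumour cannot be told apart: the neighbours' median was also high in GFP-positive replicate 1, at the 99.38th percentile of windows with a median of -2.94, but Mycl itself stood at 0.64 CPM there, in the library that lacks most genes.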
